A study of Arabidopsis thaliana with 16 samples.

How the data were processed

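Seedlings of the wild type and 7 mutants (hda6, hda19, sant1234, mbd124, esant12, arid14 and rxt3) were grown for 14 days on plates with 16 h of light at 23 °C and 8 h of dark at 22 °C, per the labels. Each genotype has 2 libraries, 16 in all, of single-end reads of 50 bp from total RNA. Per the submitters' processing notes, the authors mapped reads to TAIR10 with HISAT2 2.1.0, counted them with featureCounts and used edgeR; options, strand setting and annotation release are not stated.

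The deposited table holds 32548 genes and 1 column of normalised signal per library, and the deposited signal values are not whole numbers. Every value (100% within a relative tolerance of 1e-06) matched the value that edgeR's library-size adjustment, called pseudo-counts, gives for a whole read count, under a common dispersion of 0.0034. Running edgeR on the recovered reads gave the deposited values back to a relative difference of at most 3.8e-10. The recovered reads came to 19259579 to 19522197 per library, and the deposited totals to 18838164 to 20105682. In all, 5616 genes had no read. Because the values were scaled and adjusted by quantile before deposit, differences in total RNA per plant cannot be read from them. All 32548 identifiers were found in the TAIR10.1 RefSeq annotation. With reads of 50 bp, close gene copies can share reads, and how these were assigned is not stated.

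Before the data were examined, the grouping, comparisons, tests, gene lists, naming rule and alternatives were fixed, with edgeR on raw counts as the test and limma as the fallback where the values are normalised. The values being normalised, the fallback was used: limma 3.58.1 with a trend (R 4.3.3) on log2 of the deposited value plus 1, all 16 libraries in 1 fit of 8 genotypes (8 residual and 6.06 prior degrees of freedom), for genes with a value of at least 10 in at least 2 libraries (20846 genes). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Counts from edgeR 4.0.16 on the recovered reads were seen before the fallback was run and are given as an alternative. Each mutant was tested against wild type, and all 21 pairs of mutants against each other, of which the 7 named in the plan are described. Correlations of deviations between libraries of 1 replicate number ran from -0.19 to 0.29 over 28 pairs of genotypes, 13 of them over 0.1. The plan had no block, and a replicate block was run as an alternative.

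Gene lists numbered 22, covering salicylic acid and defence, abscisic acid, drought and cold, jasmonate and ethylene, heat shock, oxidative stress, wound response, phosphate starvation, seed maturation, flowering time, photosynthesis, anthocyanin, aliphatic and indole glucosinolates, cell cycle, auxin, senescence, the circadian clock, root markers, floral organ identity, deacetylase complex subunits, housekeeping and transposon-related genes. The last holds the genes whose annotated product contains the letters "transpos", a wording chosen from the annotation after the data came, without their expression. Lists were tested with camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over 154 tests, with an estimated correlation and fry as alternatives. The alternative with an estimated correlation was stricter even for lists whose estimate was 0.

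The genes named are those a mutant is named for, the 8 with the largest log2 fold changes in each direction among called genes with at least 5 CPM and both mutant libraries on 1 side of both wild-type libraries, up to 3 called members per direction of each list with a camera call or at least 2 called members, and for the comparison of mutants the 8 genes higher and the 8 lower in most mutants. The same rule was extended to pairs of mutants after the data were seen, and the text prints a selection. Folds against 0 reads use a floor of 3 reads per library, and 1 to 3 reads are given with a 95% exact interval of the ratio. Overlaps between mutants are set beside the product of the list sizes over the genes tested, and beside 50 simulations of unchanged groups.

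The procedure was tested on simulated data with known changes: in hda6, with 20846 genes, 2 of 50 genes changed 1.25-fold were called, 30 of 50 at 1.5-fold, 31 of 50 at 2-fold and 44 of 50 at 4-fold, and 10 unchanged genes were called. No other gene was changed in simulated hda6, while the real hda6 comparison called 2343 genes higher and 2609 lower. With so few changed genes the adjusted threshold is stricter, so these shares need not hold for the real data. In the list test on simulated data, 0 of 20 unchanged sets were called. Simulated genes were drawn independently, while the real lists had estimated correlations up to 0.63 (wound response). This test could therefore not show false calls that come from correlated members. Alternatives were median-of-ratios factors, 2 other filters, a fit of 2 genotypes, a replicate block, a log2 fold change of at least 1, a pseudocount of 0.1, DESeq2 1.42.0 and edgeR on recovered reads, and leaving out each library. A fit without ribosomal RNA genes was also run, and its counts are not given. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.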

Results

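RNA was sequenced from 14-day-old Arabidopsis thaliana seedlings of the wild type and of 7 mutants, grown on plates under 16 h of light and 8 h of dark. The mutants are named for components of, or proteins linked to, complexes of RPD3-type histone deacetylases, enzymes that remove acetyl groups from histones and are associated with repression of transcription. They are hda6 and hda19, in 2 deacetylases; sant1234 and esant12, in 4 and 2 genes named for the SANT domain; mbd124, in 3 methyl-CpG-binding domain genes; arid14, in 2 ARID domain genes; and rxt3. Each of the 8 genotypes had 2 libraries, 16 in all, of single-end reads of 50 bp. The labels do not say whether the 2 libraries of a genotype came from separate pools of plants, so each p-value measures only the spread between these samples.

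The deposited normalised values were turned back into whole reads for depth. Wild type held 19493628 and 19522197 reads per library, hda6 19259579 and 19309833, hda19 19443073 and 19477668 and sant1234 19375969 and 19293114. The mbd124 libraries held 19317514 and 19420606, esant12 19408428 and 19422323, arid14 19408301 and 19437179 and rxt3 19455916 and 19413013. Values below are means of the deposited normalised read counts ± SD (n = 2 per genotype), log2 fold changes are mutant minus wild type, and adjusted p-values are from limma over 20846 tested genes unless another tool is named. The genes printed here are a selection from a longer set named by a rule written before the data were examined, and they were picked after the results were seen, in part because they kept their call under the alternatives tried. Over the whole set, 769 of 3476 tests without 1 library lost the call, as did 106 of 834 with DESeq2. The DESeq2 figure leaves out those of the 869 tests for which DESeq2 gave no adjusted p. Up to 5658 genes in a mutant comparison had none, and the DESeq2 counts of genes treat them as not called. Count intervals and floors cover counting error only.

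The genes the mutants are named for were read first, as a check of the labels. HDA19 (chromosome 4, 17896278 to 17899509 in TAIR10.1) was nearly absent from the hda19 libraries, at 2.93 ± 2.74 against 2155 ± 94.8 in wild type, or 0.136% (adjusted p = 4.7e-10). In mbd124, MBD1 stood at 1.03 ± 0.0117 against 219 ± 14.1 in wild type, with 2 reads against 439 and a 95% exact counting interval of the ratio of 0.00055 to 0.0166. MBD4 stood at 6.23% of wild type (adjusted p = 9.7e-07) and MBD2 at 37.6% (adjusted p = 9.5e-08). HDC1, which the reference lists as the RXT3-like gene, fell to 29.6% in rxt3 (adjusted p = 3e-10). ARID1 fell to 49.7% in arid14 (adjusted p = 6e-04), while ARID4 was at 92% (adjusted p = 0.32). HDA6 transcript was at 113% of wild type in hda6 (adjusted p = 0.14), so transcript level does not check the hda6 label, nor the ARID4 part of arid14. The reference names no SANT1 to SANT4 or ESANT1 and ESANT2 locus, so these were not read.

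**Figure D1:**
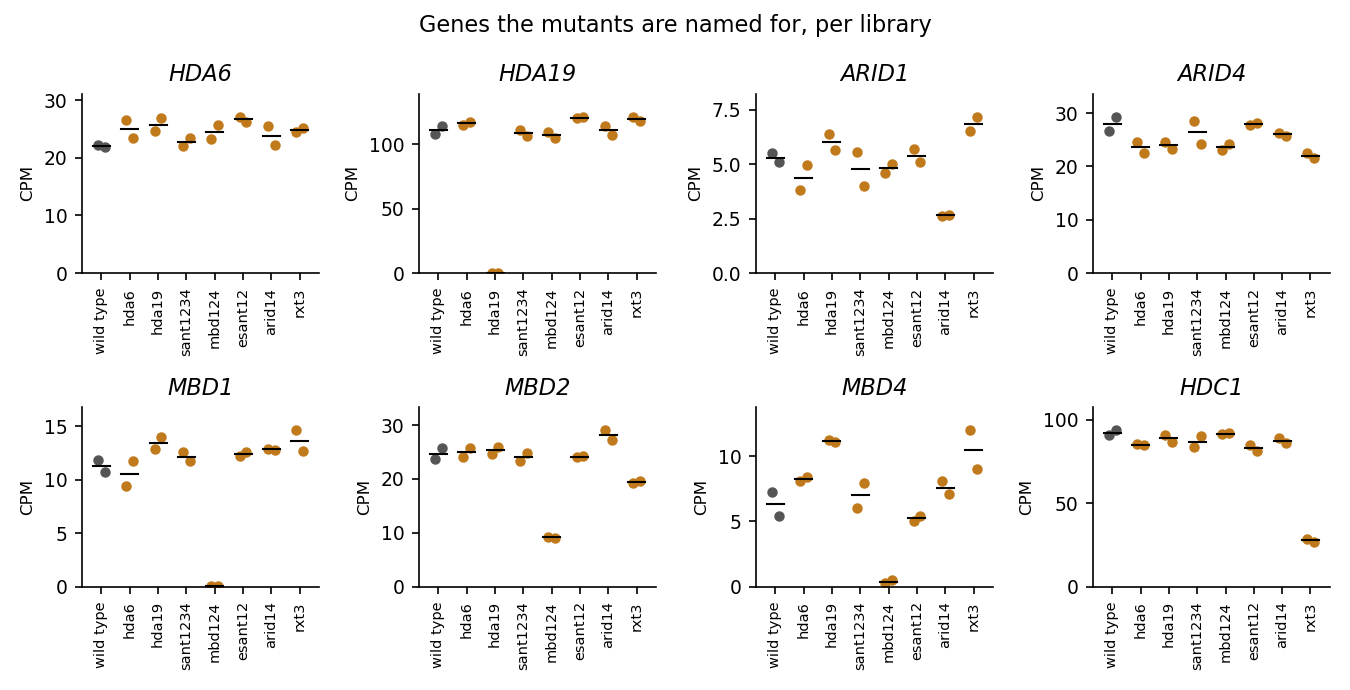
Counts per (CPM) of each gene a mutant is named for, in each of the 16 libraries. Points are libraries, grey for wild type and orange for mutants, and lines are the means of 2; HDA19, MBD1 and MBD4 lie near 0 in their mutants, while HDA6 and ARID4 do not.

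Every mutant differed from wild type at many genes, from 986 higher and 1098 lower in mbd124 to 4644 higher and 5197 lower in rxt3. Between them, 2343 were higher and 2609 lower in hda6, 2925 were higher and 3372 lower in hda19, 1779 were higher and 2355 lower in sant1234, 2402 were higher and 2990 lower in esant12 and 3143 were higher and 3592 lower in arid14. Most differences were below 2-fold: with a log2 fold change of at least 1 required, mbd124 kept 110 higher and 41 lower genes and rxt3 1059 and 494. At that size 751 genes were higher and 129 lower in hda6, and 267 and 389 in esant12. Over all called genes every mutant had more lower than higher, but this side turned under some settings. With a log2 fold change of at least 1 required it turned in all mutants but esant12. In hda6 it did so with DESeq2 (1551 higher and 1349 lower), edgeR (2574 and 2310), without a filter (2455 and 2401) and without wild-type replicate 2 (1782 and 1533). With edgeR it also turned in hda19 (3175 and 3173) and rxt3 (5084 and 4720). In mbd124 it turned in a fit of 2 genotypes (61 and 55), without mbd124 replicate 1 (532 and 523) and without wild-type replicate 2 (665 and 497). The test of all 7 mutants together called 14964 genes.

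**Figure D2:**
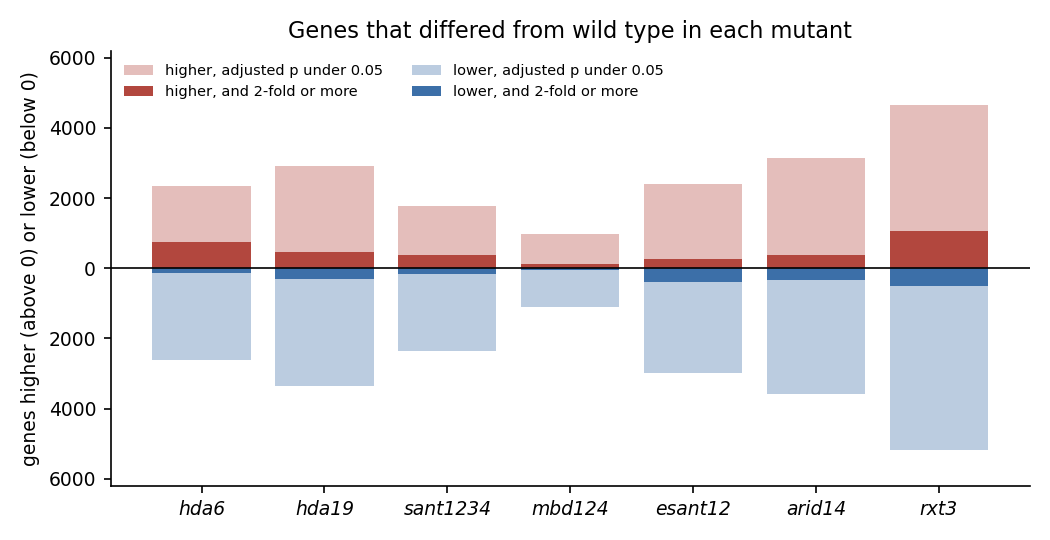
Number of genes higher (above 0) or lower (below 0) than wild type in each mutant at an adjusted p under 0.05 in limma. Pale bars are all such genes and dark bars those with a log2 fold change of at least 1 in size; hda6 has 751 dark-bar genes higher and 129 lower, and esant12 267 and 389.

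The hda6 comparison asks which transcripts depend on the deacetylase HDA6. Its strongest changes were loci silent in wild type. AT3G44265 (chromosome 3, 15955138 to 15956246), a beta-galactosidase-like gene, reached 1604 ± 12 with 0 wild-type reads, at least 531-fold higher on a floor of 3 reads per library (adjusted p = 1e-08). AT2G03965, of unknown function, reached 3445 ± 107 against 1.99 ± 1.41, a 1730-fold difference (adjusted p = 1.6e-07), and AT2G01422, also with 0 wild-type reads, was at least 205-fold higher. Of the 751 genes higher by a log2 fold change of at least 1, 153 (20.4%) had a wild-type mean under 5 and an hda6 mean of at least 20, limits set after the data were seen. The floral repressors MAF4 and MAF5, relatives of FLC, also rose, to 92.6 ± 1.11 against 9.97 ± 1.38 in wild type (adjusted p = 8.6e-05) and 81.2 ± 34.3 against 11.96 ± 1.45 in wild type (adjusted p = 4.2e-05). The sugar transporter gene SAG29 fell 5.53-fold, to 402 ± 14.1 against 2226 ± 355 in wild type (adjusted p = 2.4e-08), MRN1, a marneral synthase gene, fell 5.43-fold (adjusted p = 0.0016) and EXL5 3.47-fold (adjusted p = 9.9e-06).

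Of 16 tested genes of the early mechanical and wound response, 10 were higher and 1 lower (11 and 2 adjusted over the list alone), with a camera adjusted p = 0.000409 and an adjusted p = 0.733 with an estimated correlation. WRKY40, a regulator of defence and wound responses, rose to 1141 ± 255 against 341 ± 82.3 in wild type (adjusted p = 0.00014) and the calmodulin-like gene CML38 had a log2 fold change of 1.59 ± 0.28 SE (adjusted p = 0.0012). Of 27 tested photosynthesis genes, 11 were higher and 1 lower (15 and 2 adjusted over the list alone), with a camera adjusted p = 0.00252 and an adjusted p = 0.748 with an estimated correlation. The light-harvesting gene LHCB1.4 had a log2 fold change of 0.84 ± 0.14 SE. Of 27 tested subunits of histone deacetylase complexes, 0 were higher and 10 lower (0 and 11 adjusted over the list alone), with a camera adjusted p = 0.000691 and an adjusted p = 0.181 with an estimated correlation. The plant-specific deacetylase genes HD2A and HD2B fell by 0.5 and 0.41 on the log2 scale. Of 21 tested phosphate starvation genes, 4 were higher and 1 lower (4 and 1 adjusted over the list alone), with a camera adjusted p = 0.0348 and an adjusted p = 0.733 with an estimated correlation. Of 15 tested aliphatic glucosinolate genes, 5 were higher and 0 lower (5 and 1 adjusted over the list alone), with a camera adjusted p = 0.0443 and an adjusted p = 0.661 with an estimated correlation. Of 20 tested transposon-related genes, 5 were higher and 1 lower (5 and 1 adjusted over the list alone), with a camera adjusted p = 0.041 and an adjusted p = 0.41 with an estimated correlation. The non-LTR retrotransposon gene AT2G41590 rose to 64.5 ± 5.04 with 0 wild-type reads (adjusted p = 1.6e-06). Fisher's exact test (2-sided) of transposon-related genes among the genes higher in hda6 gave 25% against 11.2% of all tested genes, an odds ratio of 2.64, p = 0.066 and an adjusted p of 0.54. Without the filter on low values it gave 11 of 40, or 27.5% against 9.1%, with an adjusted p of 0.0094. The deposited table holds 1 gene annotated as a pseudogene, against 4851 in the reference. Transposon loci annotated that way could therefore not be tested, and neither result speaks for transposons at large. Of 66 transposon-related genes in the table, 20 passed the filter. AT3G30820 and AT2G16676, at 0 in every other genotype, passed it only through hda6. Members silent elsewhere could enter only as higher in hda6, which tilts the list call and the Fisher share upward. Without the filter a gene still needed a read in some library. The other 16 lists were not called in hda6 (camera adjusted p from 0.0714 to 0.925), and over the camera alternatives the adjusted p of the called lists ran from 0.000152 to 0.748, and with fry, which tests a list against no change, from 2.99e-07 to 0.14. The transposon-related call was also lost with a replicate block (adjusted p = 0.0523). The calls of 4 lists were lost when 1 library was left out: the phosphate starvation list (0.162 without wild-type replicate 2 and 0.0824 without hda6 replicate 1), the photosynthesis list (0.051 without hda6 replicate 1), the aliphatic glucosinolate list (0.0963 without wild-type replicate 2 and 0.258 without hda6 replicate 1), the transposon-related genes list (0.0606 without hda6 replicate 1). The counts of hda6 genes changed by more than 1.5 times to 1551 higher and 1349 lower with DESeq2, 1455 higher and 1482 lower without wild-type replicate 1, 1164 higher and 1226 lower without hda6 replicate 2 and 1533 lower without wild-type replicate 2.

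**Figure D3:**
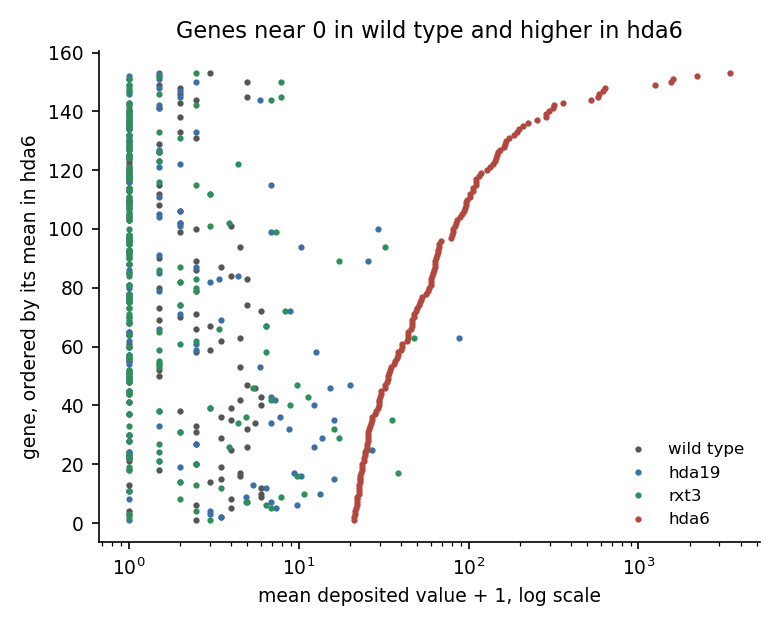
Mean deposited value plus 1, on a log axis, of the 153 genes near 0 in wild type and higher in hda6, 1 gene per line of points, ordered by the hda6 mean. The median over the genes is 51.92 in hda6, 0.5 in wild type, 0.49 in hda19 and 0 in rxt3 (means of 2 libraries).

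The hda19 comparison asks the same of HDA19. M17, a late embryogenesis abundant protein gene, reached 1009 ± 272 against 122 ± 75.2 in wild type (8.29-fold, adjusted p = 6.6e-05). The defensin-like gene AT3G59930 rose 6.7-fold (adjusted p = 1.4e-05) and the anthocyanin biosynthesis genes DFR and LDOX rose to 636 ± 92.2 against 111 ± 56.8 in wild type (adjusted p = 0.00031) and 418 ± 24.2 against 97.6 ± 50.5 in wild type (adjusted p = 0.001). ESM1, which affects the products of glucosinolate breakdown, fell 8.17-fold, to 2007 ± 94.6 against 16406 ± 482 in wild type (adjusted p = 1.6e-09). MRN1 fell to 9.31 ± 3.302 (adjusted p = 5.5e-06), the expansin-like gene EXLB1 to 9.82 ± 1.61 against 279 ± 9.63 in wild type (adjusted p = 9.6e-10) and the cold-induced gene KIN1 6.5-fold (adjusted p = 5.2e-05). MAP1D, a methionine aminopeptidase gene 439 kb from HDA19 on chromosome 4, fell to 17.2 ± 9.47 against 1083 ± 38.6 in wild type (adjusted p = 9.6e-10), and PLP4, which overlaps it, had a log2 fold change of -1.46 (adjusted p = 0.011). The other tested genes nearest MAP1D were not called. Whether the MAP1D locus is itself altered in the hda19 line was not tested.

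In hda19, of 15 tested aliphatic glucosinolate genes, 0 were higher and 10 lower (0 and 12 adjusted over the list alone), with a camera adjusted p = 4.17e-05 and an adjusted p = 0.289 with an estimated correlation. The regulators MYB76 and MYB29 fell by 1.48 and 1.07 on the log2 scale, and the biosynthesis gene CYP79F1 by 0.94. Among 28 tested jasmonate and ethylene genes, 14 were higher and 2 lower, or 14 and 2 adjusted over the list alone (camera adjusted p = 0.00666, adjusted p = 0.661 with an estimated correlation). Among them, HEL, a pathogenesis-related gene, had a log2 fold change of 1.79 ± 0.31 SE and the defensin gene PDF1.2c rose 6.8-fold (adjusted p = 0.005), though close PDF1.2 copies can share reads. Among 16 tested wound response genes, 9 were higher and 0 lower, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.00252, adjusted p = 0.733 with an estimated correlation). ERF6, an ethylene response factor gene, had a log2 fold change of 1.46 ± 0.24 SE. Among 13 tested senescence genes, 6 were higher and 1 lower, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0446, adjusted p = 0.733 with an estimated correlation). The other 18 lists were not called in hda19 (camera adjusted p from 0.0623 to 0.982), and over the camera alternatives the adjusted p of the called lists ran from 3.42e-05 to 0.733, and with fry, which tests a list against no change, from 0.000102 to 0.091. The senescence call was lost (adjusted p = 0.0665 without wild-type replicate 1 and 0.196 without hda19 replicate 2). The counts of hda19 genes changed by more than 1.5 times to 1928 higher and 2222 lower with DESeq2, 1367 higher and 1723 lower in a fit of 2 genotypes alone, 1904 higher without wild-type replicate 1 and 1791 higher and 2240 lower without hda19 replicate 2.

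The sant1234 comparison asks which transcripts differ in a mutant of 4 genes named for the SANT domain. AT3G53870, a ribosomal protein S3 family gene (chromosome 3, 19951424 to 19953018), fell 21.5-fold, to 300.0 ± 11.5 against 6458 ± 239.9 in wild type (adjusted p = 5.2e-16). None of the 8 tested genes nearest it had as large a change, the most being a log2 fold change of 1.3 at AT3G53840. Whether this gene is itself altered in the mutant line was not tested, as the reference does not name the mutated loci. The defence genes PR2, a beta-1,3-glucanase, and AIG1 fell 10.6-fold (adjusted p = 0.00024) and 15.8-fold (adjusted p = 0.00015), and QQS, a regulator of starch content, fell 11.7-fold, to 18.4 ± 2.13 against 216 ± 8.499 in wild type (adjusted p = 6.4e-05). The floral repressors MAF5 and MAF4 rose to 100.2 ± 3.46 against 11.96 ± 1.45 in wild type (adjusted p = 3.2e-05) and 75.7 ± 15.5 against 9.97 ± 1.38 in wild type (adjusted p = 3e-04), and ORA47, an activator of jasmonate synthesis, rose 4.99-fold (adjusted p = 0.00054).

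In sant1234, of 28 tested jasmonate and ethylene genes, 18 were higher and 0 lower (21 and 1 adjusted over the list alone), with a camera adjusted p = 2.85e-11 and an adjusted p = 0.181 with an estimated correlation. The lipoxygenase genes LOX4 and LOX3, of jasmonate synthesis, had log2 fold changes of 1.95 ± 0.15 and 1.54 ± 0.15 (SE). Of 30 tested salicylic acid and defence genes, 1 was higher and 13 lower (1 and 13 adjusted over the list alone), with a camera adjusted p = 0.00111 and an adjusted p = 0.741 with an estimated correlation. Among 21 tested phosphate starvation genes, 0 were higher and 10 lower, or 0 and 12 adjusted over the list alone (camera adjusted p = 9.05e-05, adjusted p = 0.661 with an estimated correlation). IPS1, a non-coding RNA of that response, and the galactolipid synthase gene MGD3 fell by 1.21 and 1.07 on the log2 scale. Among 16 tested heat shock genes, 1 was higher and 9 lower, or 1 and 9 adjusted over the list alone (camera adjusted p = 0.00109, adjusted p = 0.41 with an estimated correlation). The heat shock factor gene HSFA2 fell to 19.4 ± 2.105 against 77.8 ± 10.2 in wild type. Among 27 tested photosynthesis genes, 16 were higher and 1 lower, or 19 and 1 adjusted over the list alone (camera adjusted p = 1.91e-06, adjusted p = 0.733 with an estimated correlation). LHCB1.4 had a log2 fold change of 1.08 ± 0.14 SE. Among 16 tested wound response genes, 8 were higher and 0 lower, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.000694, adjusted p = 0.733 with an estimated correlation). WRKY40 had a log2 fold change of 1.62 ± 0.24 SE. Among 33 tested abscisic acid, drought and cold genes, 6 were higher and 13 lower, or 6 and 15 adjusted over the list alone (camera adjusted p = 0.00765, adjusted p = 0.733 with an estimated correlation). The cold-induced gene KIN2 fell by 0.95 on the log2 scale. Among 27 tested deacetylase complex subunits, 0 were higher and 9 lower, or 0 and 11 adjusted over the list alone (camera adjusted p = 0.00121, adjusted p = 0.181 with an estimated correlation). Among 18 tested auxin response genes, 5 were higher and 1 lower, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0226, adjusted p = 0.748 with an estimated correlation). Among 20 tested root markers, 3 were higher and 0 lower, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.733 with an estimated correlation). The other 12 lists were not called in sant1234 (camera adjusted p from 0.0547 to 0.982), and over the camera alternatives the adjusted p of the called lists ran from 7.68e-13 to 0.748, and with fry, which tests a list against no change, from 0.000157 to 0.162. Calls were lost when 1 library was left out for the auxin response list (0.0775 without wild-type replicate 1) and the root markers list (0.081 without wild-type replicate 1 and 0.0854 without sant1234 replicate 2). The counts of sant1234 genes changed by more than 1.5 times to 1151 higher and 1430 lower with DESeq2, 1054 higher and 1553 lower in a fit of 2 genotypes alone, 1099 higher and 1445 lower without wild-type replicate 1, 1177 higher and 1330 lower without wild-type replicate 2, 969 higher and 1328 lower without sant1234 replicate 1 and 865 higher and 1280 lower without sant1234 replicate 2.

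The mbd124 comparison asks the same of 3 methyl-CpG-binding domain genes. It had the fewest changed genes of the 7 mutants in this test. WRKY53, a defence and senescence regulator, and NCED3, of abscisic acid synthesis, rose to 364 ± 91.9 against 96.7 ± 27.1 in wild type (adjusted p = 0.0018) and 784 ± 26.3 against 219 ± 25.4 in wild type (adjusted p = 3.7e-05), and WRKY40 rose 2.97-fold (adjusted p = 0.0012). The cysteine proteinase gene AT2G27420 fell 2.74-fold, to 314 ± 36.99 against 860.0 ± 92.9 in wild type (adjusted p = 0.00041). Of 27 tested photosynthesis genes, 18 were higher and 1 lower (19 and 1 adjusted over the list alone), with a camera adjusted p = 7.89e-11 and an adjusted p = 0.661 with an estimated correlation. The light-harvesting genes LHCB1.4 and LHCB1.2 had log2 fold changes of 1.06 ± 0.14 and 0.75 ± 0.10 (SE), while RBCS1B, a Rubisco small subunit gene, fell by 0.44. Among 28 tested jasmonate and ethylene genes, 8 were higher and 0 lower, or 14 and 2 adjusted over the list alone (camera adjusted p = 8.66e-05, adjusted p = 0.52 with an estimated correlation). LOX4 had a log2 fold change of 1.4 ± 0.15 SE and VSP2, a vegetative storage protein gene, one of 1.28 ± 0.21 SE. Among 16 tested heat shock genes, 0 were higher and 5 lower, or 0 and 8 adjusted over the list alone (camera adjusted p = 0.00111, adjusted p = 0.41 with an estimated correlation). The chaperone genes HSP70 and HSP90.1 fell by 0.94 and 0.79 on the log2 scale. Among 16 tested wound response genes, 6 were higher and 0 lower, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.00152, adjusted p = 0.733 with an estimated correlation). Among 18 tested auxin response genes, 3 were higher and 0 lower, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.0465, adjusted p = 0.76 with an estimated correlation). The other 17 lists were not called in mbd124 (camera adjusted p from 0.0672 to 0.982), and over the camera alternatives the adjusted p of the called lists ran from 1.6e-13 to 0.76, and with fry, which tests a list against no change, from 0.00434 to 0.26. The auxin call was lost (adjusted p = 0.193 without wild-type replicate 1 and 0.256 without mbd124 replicate 2). The counts of mbd124 genes changed by more than 1.5 times to 61 higher and 55 lower in a fit of 2 genotypes alone, 425 higher and 461 lower without wild-type replicate 1, 532 higher and 523 lower without mbd124 replicate 1, 385 higher and 398 lower without mbd124 replicate 2 and 497 lower without wild-type replicate 2.

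The esant12 comparison asks about 2 further proteins named for the SANT domain. AT2G03470, an ELM2 domain gene (chromosome 2, 1045446 to 1047744), rose 34.9-fold, to 26122 ± 929 against 748 ± 20 in wild type (adjusted p = 1.1e-15). Whether this locus is itself altered in the mutant line was not tested, since the mutated loci are unnamed in the reference. The cold-response regulator CBF2 rose to 266 ± 103 against 40.9 ± 24.1 in wild type (adjusted p = 0.0026), and THI2.2, a thionin gene, rose 3.79-fold (adjusted p = 4.8e-07). Genes that fell include MRN1, to 3.07 ± 1.39 (adjusted p = 1.3e-06), the drought-responsive gene RD29B to 52.9 ± 5.73 against 515 ± 72.3 in wild type (adjusted p = 0.0029), and the lipid transfer gene LTP4 to 56.6 ± 61.8 against 396 ± 102 in wild type (adjusted p = 0.0039). PR1, a marker of salicylic acid signalling, fell 7.33-fold (adjusted p = 0.00058) and the defensin gene PDF1.3 10.5-fold (adjusted p = 0.00051).

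In esant12, of 16 tested heat shock genes, 0 were higher and 10 lower (0 and 10 adjusted over the list alone), with a camera adjusted p = 3.72e-05 and an adjusted p = 0.289 with an estimated correlation. HSP17.6II, a small heat shock protein gene, had 1 read against 45 in wild type (95% counting interval of the ratio 0.000551 to 0.13, adjusted p = 4.1e-05). Of 27 tested photosynthesis genes, 19 were higher and 2 lower (19 and 3 adjusted over the list alone), with a camera adjusted p = 1.91e-06 and an adjusted p = 0.733 with an estimated correlation. LHCB1.4 had a log2 fold change of 1.29 ± 0.14 SE and RBCS1B one of -0.81 ± 0.08 SE. Among 28 tested jasmonate and ethylene genes, 13 were higher and 6 lower, or 13 and 6 adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.724 with an estimated correlation). The median of that list was 0.48 and its mean -0.05, so mean and test differ in sign: the synthesis gene OPR3 had a log2 fold change of 1.46 ± 0.12 SE while PDF1.3 was at -3.12 ± 0.50. Among 16 tested wound response genes, 9 were higher and 2 lower, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.00645, adjusted p = 0.748 with an estimated correlation). Among 30 tested salicylic acid and defence genes, 1 was higher and 9 lower, or 1 and 9 adjusted over the list alone (camera adjusted p = 0.0383, adjusted p = 0.785 with an estimated correlation). Among 27 tested cell cycle and DNA replication genes, 3 were higher and 0 lower, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.00728, adjusted p = 0.733 with an estimated correlation). The replication gene MCM3 had a log2 fold change of 0.58 ± 0.11 SE. The other 16 lists were not called in esant12 (camera adjusted p from 0.0854 to 0.947), and over the camera alternatives the adjusted p of the called lists ran from 2.42e-07 to 0.785, and with fry, which tests a list against no change, from 0.000166 to 0.26. Calls were lost when 1 library was left out for the salicylic acid and defence list (0.132 without wild-type replicate 1 and 0.343 without esant12 replicate 2), the early mechanical and wound response list (0.169 without esant12 replicate 1), the cell cycle and DNA replication list (0.217 without wild-type replicate 2). The counts of esant12 genes changed by more than 1.5 times to 1522 higher and 1906 lower with DESeq2, 1392 higher and 1878 lower in a fit of 2 genotypes alone, 1515 higher without wild-type replicate 1, 1387 higher and 1941 lower without esant12 replicate 1 and 1977 lower without wild-type replicate 2.

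The arid14 comparison asks about 2 ARID-domain proteins. The auxin-response gene IAA29 reached 1155 ± 175 against 158 ± 25.9 in wild type (7.33-fold, adjusted p = 2e-08), PIL1, a phytochrome-linked factor, 405 ± 115 against 75.3 ± 6.61 in wild type (adjusted p = 2.4e-06), and the cell-wall gene XTH15 rose 5.6-fold (adjusted p = 4.5e-06). ASN1, an asparagine synthetase gene induced in the dark, rose 5.32-fold, to 21418 ± 2774 against 4026 ± 466 in wild type (adjusted p = 8.8e-07). AT2G27420 fell 14.2-fold, to 60.4 ± 0.482 against 860.0 ± 92.9 in wild type (adjusted p = 8.6e-09), the B-box gene BBX32 fell 10.3-fold (adjusted p = 2.2e-08) and ASG4, a MYB-like gene, 7.91-fold (adjusted p = 2.9e-09).

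In arid14, of 18 tested auxin response genes, 10 were higher and 2 lower (12 and 2 adjusted over the list alone), with a camera adjusted p = 0.000721 and an adjusted p = 0.733 with an estimated correlation. GH3.5 and IAA30 had log2 fold changes of 2.1 ± 0.14 and 1.93 ± 0.32 (SE). Of 21 tested phosphate starvation genes, 14 were higher and 2 lower (14 and 2 adjusted over the list alone), with a camera adjusted p = 0.000446 and an adjusted p = 0.661 with an estimated correlation. NPC4, a phospholipase C gene, rose to 501 ± 27.8 against 195 ± 40.96 in wild type (adjusted p = 0.00067). Among 16 tested wound response genes, 1 was higher and 9 lower, or 1 and 9 adjusted over the list alone (camera adjusted p = 0.0462, adjusted p = 0.777 with an estimated correlation). The zinc finger gene ZAT10 fell by 1.7 on the log2 scale. Among 16 tested heat shock genes, 0 were higher and 9 lower, or 0 and 9 adjusted over the list alone (camera adjusted p = 0.00408, adjusted p = 0.52 with an estimated correlation). HSFA2 fell to 18.3 ± 1.96 against 77.8 ± 10.2 in wild type (adjusted p = 6.2e-05). Among 27 tested photosynthesis genes, 17 were higher and 6 lower, or 18 and 6 adjusted over the list alone (camera adjusted p = 0.00373, adjusted p = 0.75 with an estimated correlation). LHCB1.4 had a log2 fold change of 1.79 ± 0.14 SE and RBCS1B one of -0.9 ± 0.08 SE. Among 15 tested aliphatic glucosinolate genes, 0 were higher and 6 lower, or 1 and 8 adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.661 with an estimated correlation). Their regulator MYB28 fell by 0.76 on the log2 scale. The other 16 lists were not called in arid14 (camera adjusted p from 0.0583 to 0.977), and over the camera alternatives the adjusted p of the called lists ran from 8.61e-06 to 0.777, and with fry, which tests a list against no change, from 0.000595 to 0.161. The wound response call was lost (adjusted p = 0.107 without wild-type replicate 2 and 0.209 without arid14 replicate 1). The counts of arid14 genes changed by more than 1.5 times to 2014 higher with DESeq2, 1872 higher in a fit of 2 genotypes alone and 2083 higher without arid14 replicate 2.

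The rxt3 comparison asks about the RXT3-like protein HDC1, known to bind deacetylases. It had the most changed genes of the 7 mutants. The defensin genes PDF1.2a and PDF1.2c, markers of jasmonate and ethylene signalling, rose 60.3-fold, to 3606 ± 1562 against 59.8 ± 16.7 in wild type (adjusted p = 5e-06), and 84.1-fold (adjusted p = 2.9e-06), though close copies can share reads. The glutathione transferase gene GSTU3 rose 30.6-fold (adjusted p = 0.00091), the polygalacturonase gene PGAZAT 46.1-fold (adjusted p = 0.00016) and WRKY53 7.59-fold (adjusted p = 4.4e-06). RD29B fell to 67.96 ± 48.9 against 515 ± 72.3 in wild type (adjusted p = 0.0017). The flowering activator SOC1 fell to 346 ± 81.7 against 1063 ± 15.4 in wild type (adjusted p = 3.1e-07), while the floral repressor MAF5 rose to 93.1 ± 19.1 against 11.96 ± 1.45 in wild type (adjusted p = 5.4e-06).

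In rxt3, of 28 tested jasmonate and ethylene genes, 20 were higher and 1 lower (20 and 1 adjusted over the list alone), with a camera adjusted p = 4.99e-06 and an adjusted p = 0.41 with an estimated correlation. Of 19 tested anthocyanin and flavonoid genes, 12 were higher and 1 lower (13 and 1 adjusted over the list alone), with a camera adjusted p = 0.000694 and an adjusted p = 0.661 with an estimated correlation. The pigment synthesis genes DFR, UF3GT and LDOX had log2 fold changes of 3.35 ± 0.40, 3.29 ± 0.50 and 3.17 ± 0.40 (SE). Among 16 tested oxidative stress genes, 13 were higher and 2 lower, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.000474, adjusted p = 0.661 with an estimated correlation). GSTF6, a glutathione transferase gene, had a log2 fold change of 1.8 ± 0.17 SE. Among 21 tested phosphate starvation genes, 13 were higher and 0 lower, or 13 and 0 adjusted over the list alone (camera adjusted p = 0.000183, adjusted p = 0.661 with an estimated correlation). The ribonuclease gene RNS1 rose to 394 ± 25.7 against 84.7 ± 27.9 in wild type (adjusted p = 0.00017). Among 30 tested salicylic acid and defence genes, 10 were higher and 1 lower, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.0421, adjusted p = 0.788 with an estimated correlation). SARD1, a regulator of salicylic acid synthesis, had a log2 fold change of 1.9 ± 0.36 SE. Among 13 tested indole glucosinolate and camalexin genes, 7 were higher and 3 lower, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.0421, adjusted p = 0.733 with an estimated correlation). PAD3, of camalexin synthesis, had a log2 fold change of 1.75 ± 0.31 SE. Among 19 tested circadian clock genes, 4 were higher and 8 lower, or 4 and 9 adjusted over the list alone (camera adjusted p = 0.0167, adjusted p = 0.596 with an estimated correlation). The morning genes RVE1 and LHY fell by 2.2 and 0.97 on the log2 scale, while PRR7 had a log2 fold change of 0.57 ± 0.07 SE. Among 20 tested root markers, 11 were higher and 2 lower, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.0443, adjusted p = 0.733 with an estimated correlation). PLT2 had a log2 fold change of 1.74 ± 0.39 SE, while SCR fell by 0.63. Photosynthesis genes, the leaf markers, had 13 of 27 higher and 5 lower, with a median log2 fold change of 0.21 and no call (camera adjusted p = 0.0623). The other 14 lists were not called in rxt3 (camera adjusted p from 0.0545 to 0.952), and over the camera alternatives the adjusted p of the called lists ran from 4.94e-07 to 0.788, and with fry, which tests a list against no change, from 5.82e-05 to 0.171. Calls were lost when 1 library was left out for the salicylic acid and defence list (0.144 without wild-type replicate 2 and 0.103 without rxt3 replicate 1), the indole glucosinolate and camalexin list (0.0517 without wild-type replicate 1), the root markers list (0.0987 without wild-type replicate 1 and 0.0884 without rxt3 replicate 2).

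Over the 22 lists, all fixed before the data were examined but for the wording that defines transposon-related genes, 45 of 154 list tests were called by camera with a preset correlation of 0.01, and 0 held with an estimated correlation. That option changed more than the correlation. Deacetylase complex subunits had an estimated correlation of 0, below the preset, yet their adjusted p rose from 0.000691 to 0.181 in hda6. The loss of all 45 calls therefore cannot be put down to correlated members alone. The lists below were called in no mutant. Only 8 of 27 seed maturation genes, 19 of 26 flowering time genes and 6 of 9 floral organ identity genes passed the filter and were tested. Seed maturation had 0 to 1 of 8 tested members higher and 0 to 2 lower (camera adjusted p from 0.201 to 0.977). Its median log2 fold change ran from -0.31 in arid14 to 1.16 in hda6. Flowering time had 0 to 5 of 19 tested members higher and 0 to 8 lower (camera adjusted p from 0.11 to 0.662). Floral organ identity had 0 to 3 of 6 tested members higher and 0 to 1 lower (camera adjusted p from 0.0645 to 0.795). The housekeeping genes had 0 to 3 of 11 tested members higher and 0 to 2 lower (camera adjusted p from 0.211 to 0.952). Single flowering genes still passed: MAF5 was higher in hda6, sant1234 and rxt3, and SOC1 was lower in rxt3. The call of MAF5 in hda19 (higher, adjusted p = 0.021) ended without wild-type replicate 1 (0.108) or hda19 replicate 2 (0.192). That of MAF5 in arid14 (lower, adjusted p = 0.036) ended without wild-type replicate 1 (0.0717) or 2 (0.158) and without arid14 replicate 1 (0.109) or 2 (0.107). Across the mutants LHCB1.4 was higher in all 7, from 0.84 ± 0.14 SE in hda6 to 1.79 ± 0.14 SE in arid14. Median log2 fold changes in all 7 were positive for photosynthesis (0.12 to 0.4) and negative for heat shock (-0.75 to -0.16). All list tests use the same 2 wild-type libraries, so calls in several mutants are not independent and may in part come from them. Between mutants, photosynthesis ranged from 0 higher and 0 lower of 27 (hda19 against hda6) to 2 and 7 (rxt3 against hda6).

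**Figure D4:**
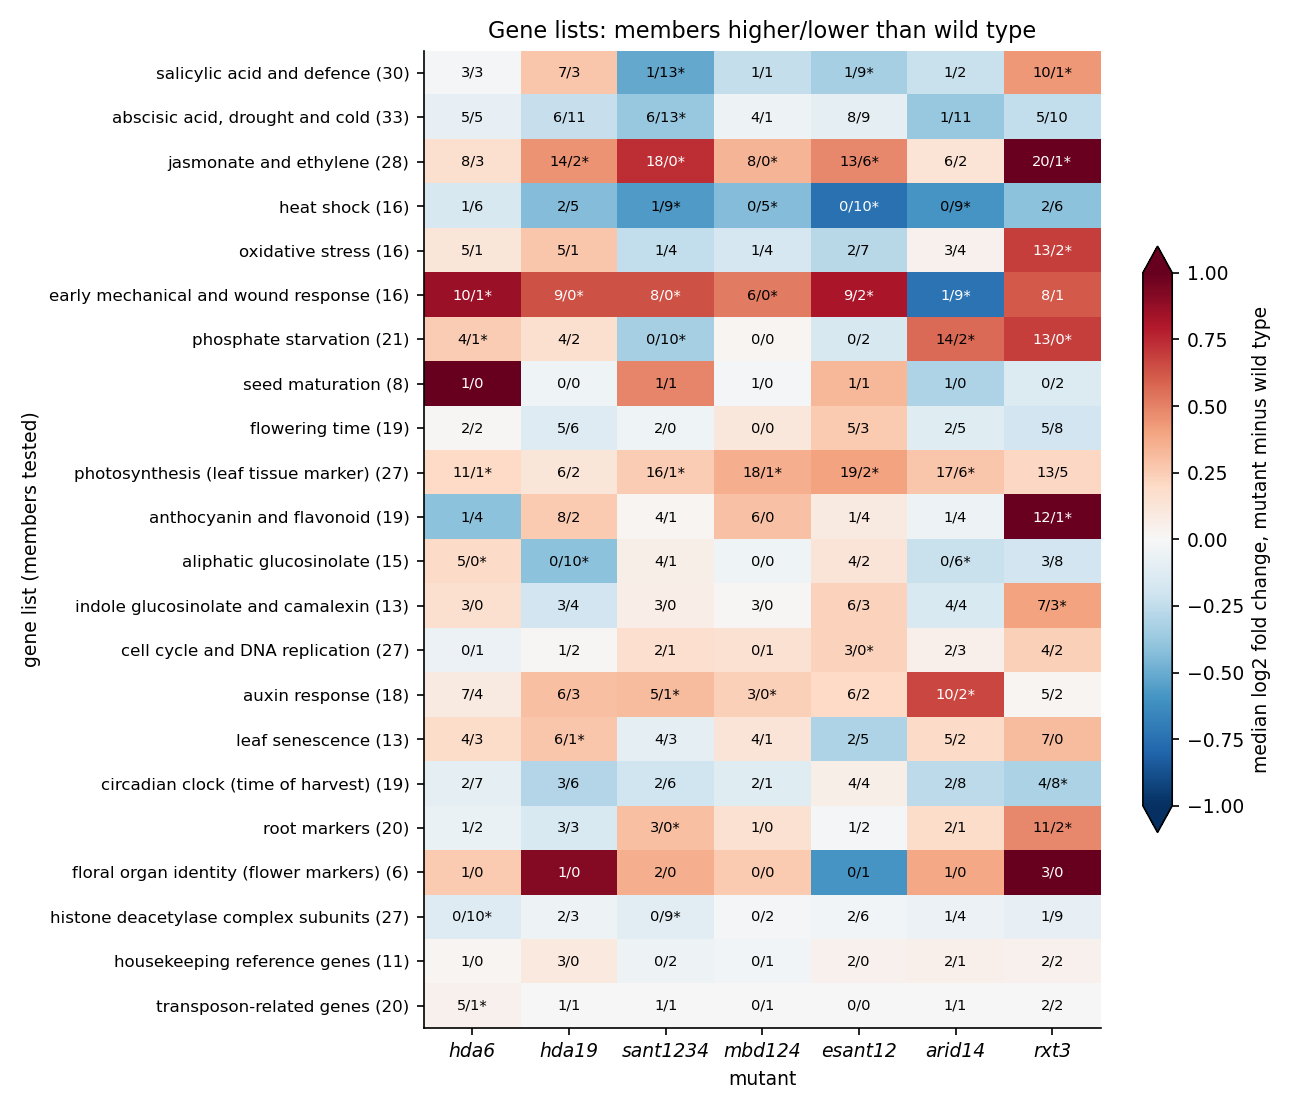
Median log2 fold change (colour, clipped at -1 and 1) of each gene list in each mutant, with the number of members higher and lower than wild type; an asterisk is a camera adjusted p under 0.05 at a preset correlation. Jasmonate and ethylene has 18 members higher and 0 lower in sant1234, 20 and 1 in rxt3, and 6 and 2 in arid14.

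The 2 deacetylase mutants were compared directly. DFR stood at 636 ± 92.2 in hda19 and 86.7 ± 19.5 in hda6 (adjusted p = 0.00017), and AT2G03965 at 0.499 ± 0.705 in hda19 and 3445 ± 107 in hda6 (adjusted p = 5.6e-08). In hda19 against hda6, aliphatic glucosinolate genes had 0 higher and 12 lower of 15 (0 and 12 adjusted over the list alone), and anthocyanin genes 9 higher and 0 lower of 19 (9 and 0 adjusted over the list alone). In all, 4972 genes (23.9% of those tested, 2323 higher and 2649 lower in hda19) differed. The number became 2996 with DESeq2, 2888 without hda6 replicate 1, 3071 without hda6 replicate 2 and 3216 without hda19 replicate 2. The rxt3 mutant was set against both. Against hda19, M17 stood at 21.1 ± 12.1 in rxt3 and 1009 ± 272 in hda19 (adjusted p = 8.5e-07) and PDF1.3 at 1297 ± 707 in rxt3 and 83.1 ± 22.04 in hda19 (adjusted p = 9.1e-05); phosphate starvation genes had 12 higher and 0 lower of 21 (15 and 0 adjusted over the list alone), and 6567 genes (31.5% of those tested, 3145 higher and 3422 lower in rxt3) differed. The number became 4030 with DESeq2, 4269 without hda19 replicate 1 and 4049 without rxt3 replicate 1. Against hda6, the secreted-protein gene AT4G33720 stood at 9353 ± 1706 in rxt3 and 153 ± 3.96 in hda6 (adjusted p = 3.6e-10), anthocyanin genes had 13 higher and 1 lower of 19 (15 and 1 adjusted over the list alone), and 9166 genes (44.0% of those tested, 4349 higher and 4817 lower in rxt3) differed.

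The mutants of SANT and methyl-CpG-binding genes had the fewest differing genes of the 21 pairs. Among the named genes, the difference with the smallest adjusted p was AT3G53870, with the same doubt about the locus itself, at 300.0 ± 11.5 in sant1234 and 5553 ± 92.9 in mbd124 (adjusted p = 1e-15). The RERE-like gene AT2G47820 stood at 34.9 ± 0.02204 in sant1234 and 137 ± 0.714 in mbd124 (adjusted p = 3e-05). Whether AT2G47820 is itself altered in the sant1234 line was not tested either, as the mutated loci are unnamed in the reference. Jasmonate and ethylene genes had 6 higher and 0 lower of 28 (18 and 0 adjusted over the list alone), and phosphate starvation genes 0 higher and 6 lower of 21 (0 and 13 adjusted over the list alone). In all, 443 genes (2.1% of those tested, 186 higher and 257 lower in sant1234) differed, 118 of them by a log2 fold change of at least 1. The number became 271 with DESeq2, 252 without a filter, 62 without sant1234 replicate 1, 81 without sant1234 replicate 2, 70 without mbd124 replicate 1 and 142 without mbd124 replicate 2. A small count does not show that the mutants act alike.

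The remaining planned pairs differed more. Between sant1234 and esant12, MRN1 stood at 465 ± 120.3 in sant1234 and 3.07 ± 1.39 in esant12 (adjusted p = 5.3e-07), MAF5 at 100.2 ± 3.46 in sant1234 and 11.3 ± 1.28 in esant12 (adjusted p = 2.7e-05), and jasmonate genes had 9 higher and 0 lower of 28 (10 and 1 adjusted over the list alone); 4442 genes (21.3% of those tested, 2261 higher and 2181 lower in sant1234) differed. The number became 2537 with DESeq2, 2405 without sant1234 replicate 1, 2260 without sant1234 replicate 2, 2293 without esant12 replicate 1 and 2803 without esant12 replicate 2. Between sant1234 and arid14, the ethylene response factor gene ERF13 stood at 112 ± 2.75 in sant1234 and 10.4 ± 6.41 in arid14 (adjusted p = 0.00015) and bHLH38, of the iron deficiency response, at 529 ± 62.4 in sant1234 and 61.8 ± 29.7 in arid14 (adjusted p = 0.00037). Wound response genes had 13 higher and 0 lower of 16 (13 and 1 adjusted over the list alone), phosphate starvation genes 0 higher and 16 lower of 21 (1 and 18 adjusted over the list alone), and 3541 genes (17.0% of those tested, 1869 higher and 1672 lower in sant1234) differed. The number became 2215 with DESeq2, 1891 without arid14 replicate 2, 1614 without sant1234 replicate 1 and 2024 without sant1234 replicate 2. Between esant12 and arid14, CBF2 stood at 266 ± 103 in esant12 and 18.3 ± 13.5 in arid14 (adjusted p = 0.00015) and PR1 at 99.2 ± 53.8 in esant12 and 1208 ± 84.3 in arid14 (adjusted p = 6.8e-05). Auxin response genes had 2 higher and 10 lower of 18 (3 and 12 adjusted over the list alone), phosphate starvation genes 0 higher and 16 lower of 21 (0 and 16 adjusted over the list alone), and 6359 genes (30.5% of those tested, 3130 higher and 3229 lower in esant12) differed. The number became 4107 with DESeq2.

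**Figure D5:**
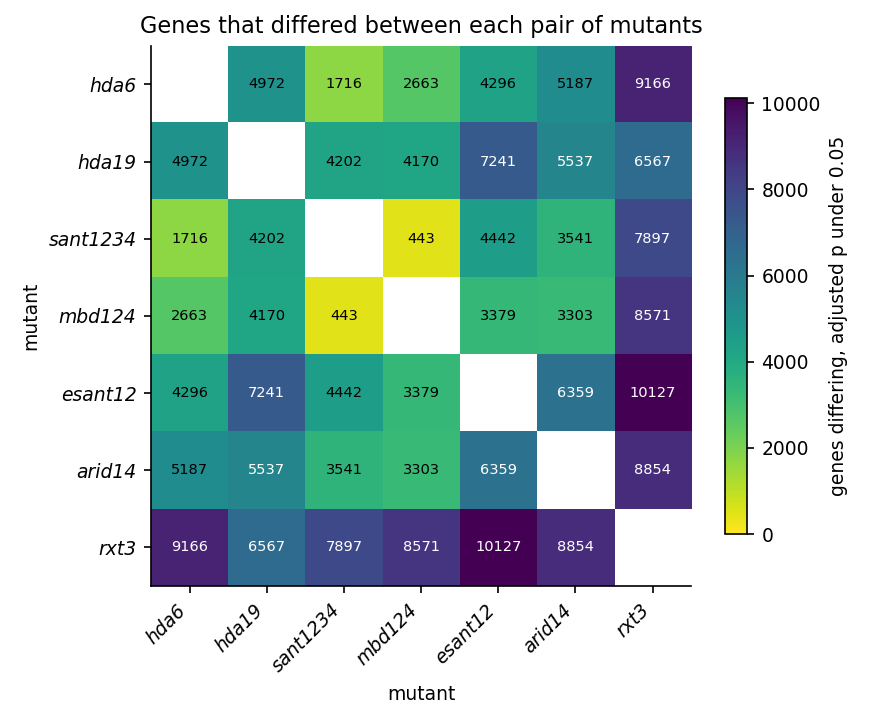
Number of genes that differed between each pair of mutants at an adjusted p under 0.05 in limma (colour and figures; 2 libraries per mutant). The pair sant1234 and mbd124 has 443, hda6 and sant1234 1716, and esant12 and rxt3 10127.

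Some genes changed alike in all 7 mutants. AT2G27420 was lower in each, with log2 fold changes from -3.81 to -1.07, as were ASG4 (-2.96 to -0.66), AT5G42760, a leucine carboxyl methyltransferase gene (-2.59 to -0.98) and cPT4, of polyprenyl synthesis (-2.55 to -0.75). AT1G17147, a VQ motif gene, was higher in each (1.59 to 3.2), as was AT1G69890 (1.3 to 2.05). In all, 176 genes were higher in all 7 mutants, against 0.00514 for independent lists, and 404 lower, against 0.0155. A set of 50 simulations of unchanged groups sharing 2 simulated wild-type libraries gave at most 4 at the unadjusted p limits that the real contrasts reached, and 0 at the adjusted threshold, where unchanged groups can hardly give a call. Every contrast uses the same wild type, so part of the excess may come from shared controls. The total of 580 fell to 269 without wild-type replicate 1, to 340 without wild-type replicate 2, to 358 with DESeq2 and to 10 with a log2 fold change of at least 1 required.

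By pairs, hda19 and rxt3 shared the most: 1911 genes were higher in both, against 652 for independent lists and 37.1 on average in simulations of unchanged groups at the p limits of the real contrasts. Lower in both were 2417, against 841 and 24.8. They had a covariance of log2 fold changes of 0.172 (0.0251 simulated), a Pearson correlation of 0.59 (0.5), a Spearman correlation of 0.59 (0.46) and 207 genes called in opposite directions. The ethylene response factor gene ERF6 and the defensin gene PDF1.2c were higher in both. For hda6 and sant1234, 1085 genes were higher in both, against 200 for independent lists and 18.9 on average in simulations of unchanged groups at the p limits of the real contrasts. Lower in both were 1380, against 295 and 11.4. They had a covariance of log2 fold changes of 0.135 (0.0252 simulated), a Pearson correlation of 0.46 (0.5), a Spearman correlation of 0.62 (0.45) and 30 genes called in opposite directions; MAF4 and MAF5 were higher in both. For sant1234 and mbd124, 721 genes were higher in both, against 84 for independent lists and 10.4 on average in simulations of unchanged groups at the p limits of the real contrasts. Lower in both were 868, against 124 and 5.7. They had a covariance of log2 fold changes of 0.0917 (0.0251 simulated), a Pearson correlation of 0.65 (0.5), a Spearman correlation of 0.68 (0.45) and 5 genes called in opposite directions. For hda19 and esant12, 858 genes were higher in both, against 337 for independent lists and 25.7 on average in simulations of unchanged groups at the p limits of the real contrasts. Lower in both were 1197, against 484 and 16.2. They had a covariance of log2 fold changes of 0.061 (0.0252 simulated), a Pearson correlation of 0.28 (0.5), a Spearman correlation of 0.29 (0.46) and 465 genes called in opposite directions. The simulations gave 0 shared calls for each pair at the adjusted threshold, where unchanged groups can hardly give a call. The counts at the p limits of the real contrasts are the ones to compare. Part of each excess may come from the shared wild type. Bracketed correlations are from simulated unchanged groups sharing wild type, so Pearson values near 0.5 do not by themselves decide likeness. The pairs above follow no stated rule. Correlations of sant1234 and arid14 were Pearson 0.54 and Spearman 0.62, and of mbd124 and arid14 0.56 and 0.62. These matched or exceeded those of hda6 and sant1234, while the covariances were lower (0.108 and 0.0855). For arid14 and rxt3, 1478 genes were higher and 2270 lower in both.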

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

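No call on a named gene changed direction with median-of-ratios factors, DESeq2, a replicate block or 1 library left out. No called list did with fry or with 1 library left out. List directions with the block and with an estimated correlation were not compared. The balance of higher and lower counts turned in some alternatives for hda6, hda19, mbd124 and rxt3, and with a log2 fold change of at least 1 in all mutants but esant12. Median-of-ratios size factors, a filter of 1 CPM in 2 libraries, a replicate block, a pseudocount of 0.1 and edgeR's quasi-likelihood test on the recovered reads (added after the data were seen) left all 22 counts of genes within 1.5 times. With a log2 fold change of at least 1 required, fewer genes can pass: 751 higher and 129 lower in hda6, 449 higher and 317 lower in hda19, 369 higher and 160 lower in sant1234, 110 higher and 41 lower in mbd124, 267 higher and 389 lower in esant12, 373 higher and 336 lower in arid14 and 1059 higher and 494 lower in rxt3, and in pairs of mutants 1042 between hda19 and hda6, 1865 between rxt3 and hda6, 951 between rxt3 and hda19, 118 between sant1234 and mbd124, 693 between sant1234 and esant12, 552 between sant1234 and arid14 and 975 between esant12 and arid14. DESeq2 gave 1551 higher and 1349 lower in hda6, 1928 higher and 2222 lower in hda19, 1151 higher and 1430 lower in sant1234, 1522 higher and 1906 lower in esant12 and 2014 higher in arid14, and in pairs 2996 between hda19 and hda6, 4030 between rxt3 and hda19, 271 between sant1234 and mbd124, 2537 between sant1234 and esant12, 2215 between sant1234 and arid14 and 4107 between esant12 and arid14; the cause was not tested. In a fit of 1 mutant and wild type alone, with 4 libraries to estimate the spread, the counts were 1367 higher and 1723 lower in hda19, 1054 higher and 1553 lower in sant1234, 61 higher and 55 lower in mbd124, 1392 higher and 1878 lower in esant12 and 1872 higher in arid14. Without a filter on low values, 252 genes differed between sant1234 and mbd124, and the transposon-related share among genes higher in hda6 passed (adjusted p = 0.0094, against 0.54), with more such genes tested.

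Leaving out 1 library at a time leaves 1 arm with a lone sample, assumed to vary like the other groups. The ranges were hda6 1164 to 1782 higher and 1226 to 1797 lower, hda19 1791 to 2287 higher and 2240 to 2903 lower, sant1234 865 to 1177 higher and 1280 to 1445 lower, mbd124 385 to 665 higher and 398 to 523 lower, esant12 1387 to 1781 higher and 1941 to 2062 lower, arid14 2083 to 2349 higher and 2663 to 2847 lower and rxt3 3663 to 3760 higher and 3995 to 4420 lower, and in pairs 2888 to 3735 between hda19 and hda6, 6770 to 7744 between rxt3 and hda6, 4049 to 5224 between rxt3 and hda19, 62 to 142 between sant1234 and mbd124, 2260 to 2803 between sant1234 and esant12, 1614 to 2439 between sant1234 and arid14 and 4244 to 4698 between esant12 and arid14. Genes changed in 1 direction in all 7 mutants numbered 10 at a log2 fold change of at least 1, 358 with DESeq2, 647 with the block, and 269 to 340 without 1 wild-type library (added after the data were seen). Counts of genes shared by pairs of mutants moved by more than 1.5 times in 25 of 42 cases with DESeq2 and in 42 of 42 at a log2 fold change of at least 1. Of the 45 list calls 0 held with an estimated correlation, 44 with the block, 30 with fry, and 156 of 180 tests without 1 library. Among the named genes, 3 of 869 tests lost the call with median-of-ratios factors, 4 of 869 with the block, 106 of 834 with DESeq2 and 769 of 3476 without 1 library. A fit without the 4 ribosomal RNA genes of the table was run, but its counts are not given here, and the values are already scaled. The table holds no organelle gene to leave out. Changed genes can be missed: in simulated data for hda6 with 20846 genes, 30 of 50 changed 1.5-fold were called, 31 of 50 changed 2-fold and 44 of 50 changed 4-fold. Far fewer genes were changed there than were called in the real data, so these shares need not hold for it. Depth and the number of libraries were not varied.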

Other observations

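Among the 153 genes near 0 in wild type and higher in hda6, SDC, an F-box gene known to be silenced by DNA methylation, had a mean of 57.9 in hda6 against 0.5 in wild type, AGO5, an Argonaute gene, 39.2 against 2, and the ovate family gene OFP9 126.8 against 0 (n = 2 per genotype). The histidine synthesis gene HISN6B had 172.1 against 1.5, and the oleosin-like genes GRP20 and GRP19 had 82.6 against 3 and 20.6 against 0. By type, 128 of the 153 are protein-coding, 22 long non-coding and 3 other non-coding RNA genes. AT3G01345 differed between the wild-type libraries, at 97.1 and 1193, was at 4454.6 and 4192.7 in hda6 and at 143.4 and 495.7 in hda19, and had values from 0 to 14 in the 10 libraries of the other mutants. These genes were singled out after their values were seen.

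For the genes changed in the same direction in all 7 mutants (176 higher and 404 lower), the test of dawn-phased genes was written before its result was seen and the test of chance at the p limits of the data only after the genes were counted. Chance deviation of the shared wild-type libraries gave at most 4 such genes in 50 simulations of unchanged groups at the unadjusted p limits of the real contrasts, but simulations leave out real effects and 161 of the 580 were called both without wild-type replicate 1 and without wild-type replicate 2, so it stays open for part of them. Another clock phase of the wild-type plants at harvest was tested with 10 dawn-phased genes, whose median lay below the 2.5th percentile of matched random lists in 2 mutants, arid14 (2.49) and rxt3 (0.47), where the prediction needed at least 5 and its exclusion at most 1. Clock phase stays open too, because that number meets neither bound and single dawn-phased genes moved both ways, with the percentiles of mbd124 and esant12 at the other end (99.9 and 99.51). A difference in growth between the wild-type plants and all mutants was not measured and may also account for these genes, which numbered 269 without wild-type replicate 1 and 340 without wild-type replicate 2.

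For the genes near 0 in wild type and higher in hda6, the bounds of the 3 tests were written before their results were seen, but the limits that define the genes were chosen after. Reads of overlapping annotated genes would need most to overlap another locus, and 19% did. Depth or scaling of the libraries would raise such genes in other mutants of the same depth, and the highest count elsewhere was 29, in rxt3, against 153. A pseudogene locus lay within 1 kb of 18.3% of them against 6.9% of genes near 0 in wild type and not called (odds ratio 3.02, Fisher p = 0.0014). Both sets had passed the filter of a value of at least 10 in at least 2 libraries. Genes this low in wild type pass it only through mutant libraries. Genes silent in all libraries are absent from the comparison, so the ratio does not set the 153 against silent genes at large. Lost silencing next to loci annotated as pseudogenes stays a hypothesis for part of the set, which this comparison cannot decide. Most members have no such neighbour, and histone marks were not measured.

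For the root markers higher in rxt3, the test was chosen only after the result was seen. A larger share of root tissue in the rxt3 libraries may account for the 11 of 20 that were higher, although 2 were called lower, SCR (-0.63 ± 0.08 SE) and SHR (-0.48 ± 0.11 SE), and the leaf markers did not fall as a group (photosynthesis genes, 13 of 27 higher and 5 lower, median 0.21, camera adjusted p = 0.0623). It is neither shown nor excluded, since leaf markers are abundant and members of both lists moved both ways. The largest rises were PLT2 (1.74 ± 0.39), CASP5 (1.36 ± 0.34) and the root-hair gene EXPA7 (1.01 ± 0.18). A change within particular root cell types was not tested, and the list call itself ended without wild-type replicate 1 (adjusted p = 0.0987) and without rxt3 replicate 2 (adjusted p = 0.0884), within a range over its alternatives of 0.0206 to 0.733 for root markers in rxt3.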
